A study of Homo sapiens with 9 samples.

How the data were processed

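Total RNA of HepG2, a human hepatoma cell line, was profiled on Affymetrix HG-U133 Plus 2.0 arrays 36 hours after transfection with a wild-type Tmprss6 cDNA, a mutant Tmprss6 cDNA or an empty vector. Each of the 3 groups had 3 arrays, and groups and replicate numbers were taken from the sample titles. Neither the amino acid change of the mutant nor the species of the cDNA was given in the sources used here. The labels do not say that the replicates of a group were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. RNA was extracted with Trizol, treated with DNase, cleaned on a column and amplified in 1 round with biotin labelling, per the labels' protocols.

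The deposited values were log2 signals, 1 per probe set and array, made by the authors with RMA (background correction, quantile normalisation and median polish of the probes), per the submitters' processing notes, which name no version. The values ran from 1.57 to 14.3 and the array medians from 5.45 to 5.51, so no further log transform, pseudocount or normalisation was applied. RMA compresses differences near the background, and an array gives no count of molecules. The number of arrays therefore limits the precision. The scanner information files of the 9 arrays were used only to code the scan day, the chip lot and the fluidics station as batches.

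The array holds 54675 probe sets, of which 62 are controls. The annotation table of the array used here lists 42898 of them, 41097 with 1 gene symbol and 1801 with several. The other 11777 are unnamed here. Symbols were updated through the Entrez gene number for 41043 probe sets, with the RefSeq gene table of assembly GRCh38.p14 as the source of names. For each symbol the probe set with the highest mean over all 9 arrays was kept, without regard to the groups, which left 19775 genes. Of these, 10523 had more than 1 probe set. The other probe sets of the called named genes were tested in a separate fit over all probe sets, described below. With the same sign, 19 of 59 passed for wild-type against vector, 35 of 77 for mutant against vector and 2 of 8 for wild-type against mutant. 6, 5 and 2 had the opposite sign, and 0 of these passed the test.

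Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 9 arrays, contrasts, eBayes, two-sided, Benjamini-Hochberg adjustment over all genes). A gene was called, and is described as having risen or fallen, at an adjusted p under 0.05. Values of genes are log2 differences with their standard errors from this fit unless named otherwise, and every adjusted p of a gene comes from it. By contrast, the other probe sets of a gene were judged by a limma fit of all 54675 probe sets, adjusted over all of these. In it some kept probe sets also missed the threshold, such as those of SLC22A16, NEO1 and RELB for wild-type against vector (limma adjusted p = 0.0542, 0.0535 and 0.0569). A moderated F test over both contrasts against the vector counted genes that differ among the 3 groups. HAMP and TMPRSS6 were also given an exact two-sided permutation test, which with 3 arrays against 3 cannot go below 0.1.

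20 gene lists holding 262 genes were fixed before the data were examined, and 235 of their genes were measured, 1 of them found through an older symbol. The lists were BMP-SMAD target genes, BMP receptors, ligands and hepcidin regulators, iron handling, IL6-STAT3 acute phase, type I interferon response, unfolded protein response, ATF4 amino acid response, heat shock, immediate early, NF-kB inflammatory, TGF-beta target genes, cholesterol synthesis, hepatocyte function, cell cycle, p53 target genes, hypoxia response, metallothioneins, transmembrane serine proteases and inhibitors, immune and endothelial cell markers, and fibroblast and stellate cell markers. Each was compared with all other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 60 tests. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. With the estimated correlation 0 lists were called in any comparison, and 6, 1 and 4 lists had an unadjusted p under 0.05 for wild-type against vector, mutant against vector and wild-type against mutant. Fry called 8, 7 and 4 lists. The median, the mean and the test of a list differed in sign in 6 of the 60 tests, of which 0 were called.

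The named genes follow a rule also fixed before the data were examined. It takes HAMP and TMPRSS6 everywhere and, in each comparison, among called genes whose groups do not overlap, the 12 largest rises and the 12 largest falls. If under 5 genes were called, the 10 smallest p-values would have replaced these. From each list it takes up to 4 members with the smallest p in any comparison. All other members named below were called members of a list or were chosen after their values were seen, and the latter are said to be so where they appear.

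The procedure was tested on simulated data with the real means and spreads of the 19775 genes and 200 changed genes in each of 20 simulations. For wild-type against vector it recovered 80.4% of 1.5-fold, 97.7% of 2-fold and 99.9% of 4-fold changes, with 5.53% false calls. For wild-type against mutant the shares were 79.3%, 98.1% and 100%, with 4.50% false calls. A list shifted by 0.3 log2 was called in 20 of 20 simulations, and 1 of 400 unshifted lists was called. The simulated genes varied independently, so these list results do not cover lists of correlated genes. In the real data the estimated correlation reached 0.641 (metallothioneins).

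No 2 arrays were near-identical. Across the genes tested, pairs of arrays of 1 group correlated at 0.996 to 0.999 and differed by a mean of 0.100 to 0.168 log2. Pairs from different groups correlated at 0.991 to 0.998. Replicate 1 of every group was scanned on day 1 and replicates 2 and 3 on day 2. The arrays of day 1 also shared a chip lot and a fluidics station. All 3 mutant arrays were run on that station, whereas replicates 2 and 3 of the wild-type and vector groups were run on another. The alternatives tried were filters on dim genes, cyclic loess and median centring, the median over probe sets, a trended robust prior, array weights, the replicate number or a batch as a block, each array left out, only the 6 arrays compared, and other thresholds. A further 3 were chosen after seeing the data, namely the arrays of scan day 2 alone, probe sets without the suffix _x_at, and a covariate of RNA quality. Probe sets with several symbols or none were left out of the gene tests and tested apart.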

Results

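HepG2 cells keep many liver functions, including expression of HAMP, the gene of the iron-regulatory hormone hepcidin. They were transfected with a cDNA of Tmprss6, which encodes the membrane serine protease matriptase-2, with a mutant version of it, or with the empty vector. Genome-wide transcript levels were measured 36 hours later on 3 arrays per group, as RMA log2 signals of 19775 genes. The comparisons asked what the wild-type cDNA changed against the vector, what the mutant cDNA changed against it, and where both cDNAs differed.

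The transfected gene was examined first. The brightest of 3 probe sets of TMPRSS6 had a log2 signal of 10.79 ± 0.07 (SD, n = 3) with the wild-type cDNA, 10.90 ± 0.19 (SD, n = 3) with the mutant cDNA and 6.37 ± 0.40 (SD, n = 3) with the vector. It was 21.3-fold higher with the wild-type cDNA (log2 difference 4.41 ± 0.16 (SE), limma adjusted p = 9.7e-08) and 23.0-fold higher with the mutant cDNA (4.53 ± 0.16 (SE), adjusted p = 7.28e-08). Wild-type minus mutant was -0.11 ± 0.16 (SE), with a 95% interval of -0.47 to 0.25. The other 2 probe sets of the gene differed from the vector by -0.03 and 0.07 with the wild-type cDNA and by 0.09 and 0.15 with the mutant cDNA, and passed no test. The increase thus rests on 1 of 3 probe sets, in all 6 arrays that carried a cDNA. On scan day 1 the wild-type and mutant arrays exceeded the vector array by 4.94 and 4.86, and on day 2 the differences were 4.15 and 4.36.

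HAMP rose with both cDNAs. Its log2 signal was 6.4 ± 0.11 (SD, n = 3) with the wild-type cDNA, 6.14 ± 0.28 (SD, n = 3) with the mutant cDNA and 5.48 ± 0.18 (SD, n = 3) with the vector, and all 6 cDNA arrays lay above the 3 vector arrays. The rise was 1.89-fold with the wild-type cDNA (0.92 ± 0.13 (SE), limma adjusted p = 0.00921) and 1.58-fold with the mutant cDNA (0.66 ± 0.13 (SE), adjusted p = 0.0206). The exact permutation p was 0.1 for both, the smallest that 3 against 3 allows. Wild-type and mutant did not differ detectably in HAMP, with a difference of 0.26 ± 0.13 (SE), a 95% interval of -0.03 to 0.55, a limma adjusted p of 0.743 and an exact permutation p of 0.3. On scan day 1 HAMP exceeded the vector array by 1.14 with the wild-type and by 0.63 with the mutant cDNA, and on day 2 by 0.81 and 0.68. With scan day as a block the adjusted p was 0.00809 and 0.0147. The wild-type call was lost without wild-type replicate 1 (adjusted p = 0.0547) or replicate 2 (adjusted p = 0.0593). The mutant call was lost without mutant replicate 2 (adjusted p = 0.0788), vector replicate 2 (adjusted p = 0.066) or vector replicate 3 (adjusted p = 0.0602), and with fluidics station as a block (0.75, adjusted p = 0.0763).

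**Figure D1:**
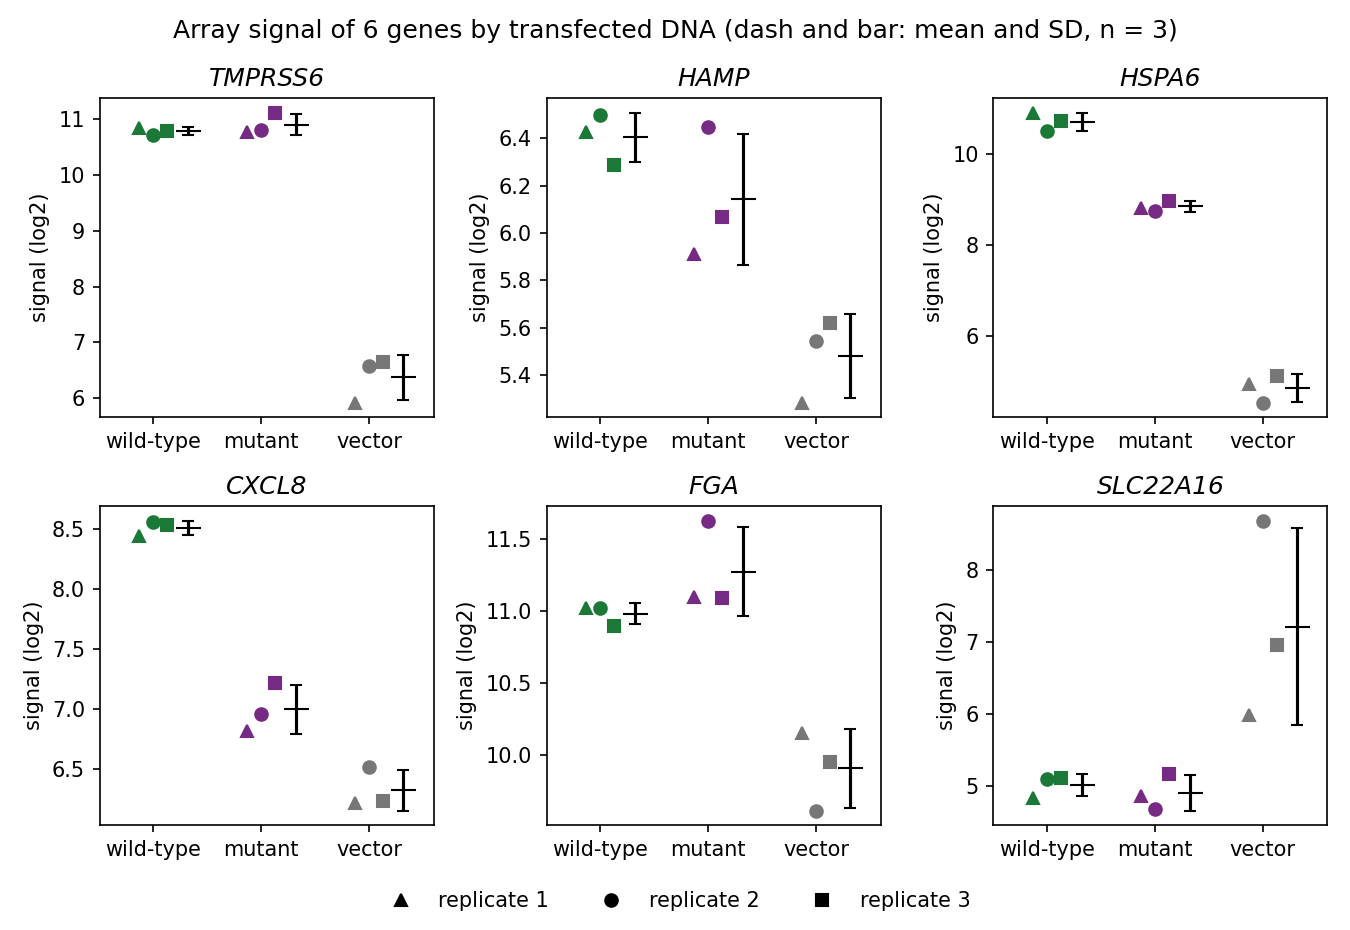
Log2 signal of TMPRSS6, HAMP, HSPA6, CXCL8, FGA and SLC22A16 (vertical axes, a separate scale for each gene) on each array by transfected DNA (horizontal axis), with symbols for the replicate number and the mean and SD of the 3 arrays as dash and bar. HAMP lies at 5.28 to 5.62 on the vector arrays and at 5.91 to 6.50 on the cDNA arrays, and HSPA6 and CXCL8 are higher with the wild-type than with the mutant cDNA.

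With the wild-type cDNA, the largest rise against the vector among the genes tested, above that of TMPRSS6 itself, was that of HSPA6, an inducible heat shock protein of the HSP70 family, at 5.87 ± 0.14 log2 (SE, 58.4-fold). Its near-identical relative HSPA7 could contribute to that signal, and the second HSPA6 probe set rose by 4.54. The second probe set of AGR2, named next, differed by 0.12 and did not pass. AGR2, a protein disulfide isomerase of the endoplasmic reticulum (2.19 ± 0.22), CXCL8, the chemokine interleukin-8 (2.19 ± 0.11), and IGFBP1, a secreted binding protein of insulin-like growth factors (1.87 ± 0.24), rose most after these. They were followed by the scaffold protein AKAP12 (1.70), the ERK phosphatase DUSP5 (1.56), the transcriptional cofactor ANKRD1 (1.52), the cytokine signalling inhibitor SOCS2 (1.51), the non-coding RNA LINC00973 (1.41), ARRDC3 (1.2) and GPRC5A (1.2). The largest falls were those of the organic cation transporter SLC22A16 (-2.19 ± 0.48, SE), the plasma protein HRG (-1.61), SPATA16 (-1.53), the proprotein convertase PCSK5 (-1.50), RAMP1, a subunit of the CGRP receptor (-1.46), MYZAP (-1.44) and ANXA13 (-1.37). RASSF8 (-1.36), the semaphorin SEMA4D (-1.29), REPS2 (-1.27), FAM167B (-1.23) and LRBA (-1.21) also fell, RASSF8 on 1 of its 4 probe sets and mostly on scan day 2 (-1.87, against -0.35 on day 1). The other falls named here were larger on day 2 as well, from ANXA13 (-1.52, against -1.05 on day 1) to HRG (-2.03, against -0.76). In the fit over all probe sets the others of SLC22A16, HRG, SEMA4D and REPS2 did not pass, nor did the kept one of SLC22A16. The others of PCSK5 and LRBA did. In all, 135 genes rose and 185 fell, and 46 of these 320 changed at least 2-fold.

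Among the fixed lists, the BMP-SMAD target genes went both ways. HAMP rose and BAMBI, a pseudoreceptor that dampens BMP and TGF-beta signals, fell (-0.81 ± 0.16, SE), while the other 7 of 9, among them ID3 (0.37) and ID2 (0.28), did not pass the test. 4 rose and 1 fell when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.0525). Of 15 measured BMP receptors, ligands and hepcidin regulators, the haemochromatosis gene HFE (-0.67 ± 0.10) and the BMP co-receptor NEO1 (-0.41 ± 0.09) fell and 13 did not pass (4 fell when adjusted over the list alone, list adjusted p = 0.189). In the fit over all probe sets 2 of 14 others of HFE and 0 of 2 others of NEO1 passed, and the kept one of NEO1 did not pass either. 0 of 17 iron handling genes changed, and 1 fell when adjusted over the list alone. STEAP3 (-0.56, adjusted p = 0.068) came closest (list adjusted p = 0.704). In the transmembrane serine proteases and inhibitors, prostasin (PRSS8, -0.54 ± 0.10) fell and the other 8 did not pass (1 rose and 1 fell when adjusted over the list alone, list adjusted p = 0.934).

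In the acute phase list the 3 fibrinogen chains FGA (1.07 ± 0.15), FGB (0.70 ± 0.14) and FGG (0.64 ± 0.10) rose and 12 of 15 did not pass (6 up and 1 down when adjusted over the list alone), and the list was called upward (camera adjusted p = 0.000456, adjusted p = 0.146 with an estimated correlation). The unfolded protein response list was called upward with a median of 0.24 (camera adjusted p = 7.3e-06, adjusted p = 0.0861 with an estimated correlation). 13 of its 14 members lay above 0, led by HYOU1 (0.32, adjusted p = 0.052), but 0 passed over all genes and 6 when adjusted over the list alone. Of the 10 genes in the heat shock list only 7 had a probe set of their own symbol and were measured. Among these the co-chaperones BAG3 (0.85 ± 0.07) and DNAJB1 (0.53 ± 0.07) rose and 5 of 7 did not pass (2 up when adjusted over the list alone). This list was called too (camera adjusted p = 0.00136, adjusted p = 0.146 with an estimated correlation). CXCL8 and RELB (0.40 ± 0.08) rose among 9 NF-kB inflammatory genes, 4 up and 1 down when adjusted over the list alone (camera adjusted p = 0.000341, adjusted p = 0.146 with an estimated correlation). Of 8 TGF-beta target genes the secreted matrix proteins THBS1 (0.88 ± 0.14) and CCN2 (0.87 ± 0.18) and the actin-binding TAGLN (0.83 ± 0.13) rose, 3 also when adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.156 with an estimated correlation). PPP1R15A (0.89 ± 0.12) and ATF3 (0.52 ± 0.08), stress-response genes of the ATF4 list, rose among 15, and 3 did when adjusted over the list alone (list adjusted p = 0.071). CCN1 (1.18 ± 0.10) was the only call among 11 immediate early genes, with 3 up and 1 down when adjusted over the list alone (list adjusted p = 0.0654).

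Cholesterol synthesis genes were shifted downward as a list, with a median of -0.15 (camera adjusted p = 0.00714, adjusted p = 0.312 with an estimated correlation), although 0 of 10 members passed, also when adjusted over the list alone. STARD4 (-0.50, adjusted p = 0.15) had the largest value. That list call was lost without vector replicate 3 (adjusted p = 0.0795). In the type I interferon list the RNA sensor RIGI fell (-0.72 ± 0.13) and 18 of 19 did not pass (2 down when adjusted over the list alone, list adjusted p = 0.769). None of the members passed, over all genes or over the list alone, among 15 hepatocyte function, 18 cell cycle, 8 p53 target, 8 metallothionein, 9 immune and endothelial and 8 fibroblast and stellate genes. Nor did any of 11 hypoxia genes pass over all genes, while 1 fell when adjusted over the list alone. The camera adjusted p of these lists was 0.786, 0.435, 0.402, 0.769, 0.704, 0.24 and 0.22.

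The ACTB probe sets gave a 3' minus 5' log2 difference, a sign of RNA quality, of 0.32 ± 0.14 (SD) with the wild-type and 0.31 ± 0.08 with the mutant cDNA against 0.41 ± 0.13 with the vector. In limma 320 genes were called for wild-type against vector, out of 2746 at an unadjusted p under 0.05. The count was 40, 46 and 71 without wild-type replicate 1, 2 and 3, and 844, 64 and 51 without vector replicate 1, 2 and 3, so each of these 6 arrays decides it. With scan day as a block 565 genes were called and within scan day 2 236. On day 1, with 1 array per group and no test, 227 of those 236 had the same sign, with a median change of 0.39 in that direction against 0.70 on day 2. The 6 called lists had medians of 0.21 and 0.19 on day 1 and day 2 (acute phase), 0.21 and 0.22 (unfolded protein response), 0.22 and 0.11 (heat shock), 0.35 and 0.14 (NF-kB), 0.21 and 0.19 (TGF-beta) and -0.11 and -0.17 (cholesterol synthesis). Array weights gave 1061 calls and fluidics station as a block 573. All 320 genes kept their direction in both, but it could not have changed. Their groups do not overlap, and wild-type and vector arrays were spread alike over the stations.

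**Figure D2:**
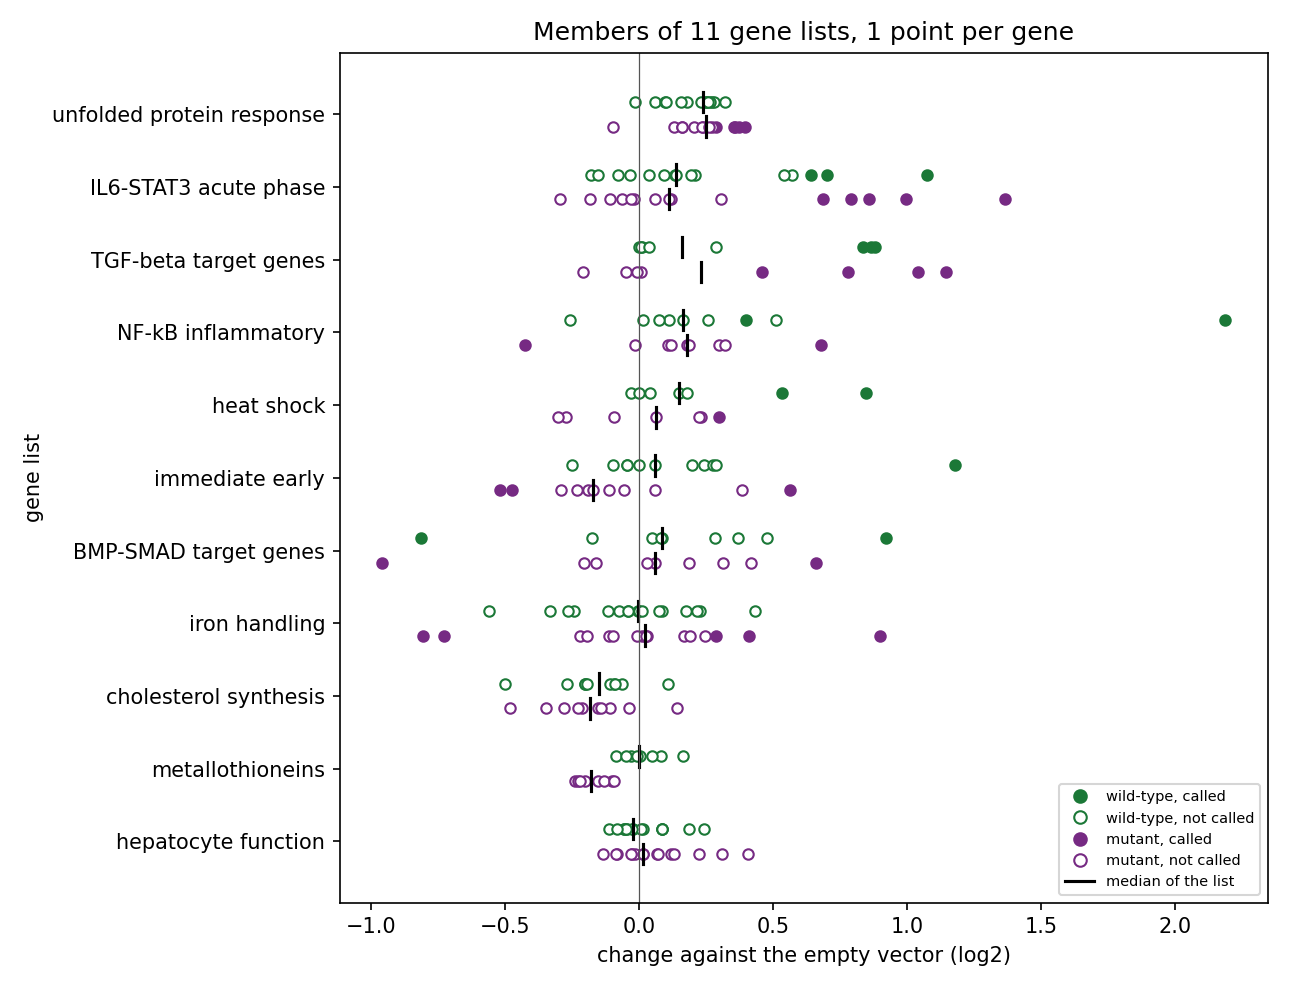
Log2 change against the vector (horizontal axis) of the measured members of 11 gene lists (vertical axis), upper row of each list for the wild-type and lower row for the mutant cDNA. Points are genes, filled where called, and black bars are list medians, such as 0.24 and 0.25 for the unfolded protein response and -0.15 and -0.19 for cholesterol synthesis.

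With the mutant cDNA, after TMPRSS6 itself, HSPA6 rose most against the vector among the genes tested (4.0 ± 0.14 log2, SE, 16-fold), followed by AGR2 (2.27 ± 0.22), IGFBP1 (1.67 ± 0.24), the ribonuclease angiogenin (ANG, 1.45 ± 0.21) and PLSCR4 (1.40 ± 0.15). AKAP12 (1.37), FGA (1.36), the thioredoxin-binding TXNIP (1.32), ANKRD1 (1.29), LINC00973 (1.23) and the cytokine TNFSF14 (1.22) completed the largest rises. The largest falls were those of SLC22A16 (-2.30 ± 0.48, SE), ALDH8A1, an aldehyde dehydrogenase (-2.29 ± 0.52), and ETNPPL, which breaks down phosphoethanolamine (-2.15 ± 0.40). RAMP1 (-2.0), HRG (-1.98), PCSK5 (-1.89), SPATA16 (-1.86), FAM167B (-1.79), the midbody protein CEP55 (-1.78), MYZAP (-1.77), LRRC40 (-1.71) and GULP1 (-1.70) fell too. In the fit over all probe sets the second ones of TNFSF14 (0.15), IGFBP1 (0.56), LRRC40 (-0.21) and SLC22A16 (-0.95) did not pass. Nor did the kept one of TNFSF14 or the others of GULP1. The others of AGR2, FGA, TXNIP, HRG and PCSK5 and most others of AKAP12 passed. In all, 345 genes rose and 463 fell, 89 of them at least 2-fold.

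Among BMP-SMAD target genes HAMP rose, BAMBI fell (-0.96 ± 0.16, SE) and 7 of 9 did not pass (3 up and 1 down when adjusted over the list alone, list adjusted p = 0.704). HFE (-0.63 ± 0.10), the protease FURIN (-0.52 ± 0.11) and NEO1 (-0.36 ± 0.09) fell among 15 BMP receptors, ligands and hepcidin regulators (2 up and 4 down when adjusted over the list alone, list adjusted p = 0.512). In the iron handling list the ferroxidase ceruloplasmin (CP, 0.90 ± 0.19), the iron exporter ferroportin (SLC40A1, 0.41 ± 0.10) and the importer SLC11A2 (0.29) rose, and the ferrireductase STEAP3 (-0.81 ± 0.14) and the haem-binding HPX (-0.73 ± 0.17) fell. The other 12 of 17 did not pass (3 up and 2 down when adjusted over the list alone), and the list was not shifted (adjusted p = 0.959). The rise of CP came mostly from scan day 2 (1.22, against 0.25 on day 1), as did the fall of HPX (-0.99, against -0.22). The changes of STEAP3 and SLC40A1 were larger on day 2 too. PRSS8 fell (-0.47 ± 0.10) and the protease inhibitor SPINT1 rose (0.40 ± 0.09) among 9 transmembrane proteases and inhibitors (2 up and 1 down when adjusted over the list alone, list adjusted p = 0.704).

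FGA, FGB (0.86 ± 0.14), FGG (0.79 ± 0.10), HP (0.69) and ORM1 (1.0 ± 0.17), all secreted acute phase proteins, rose among 15, with 6 up and 1 down when adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.254 with an estimated correlation), a call lost within scan day 2 (adjusted p = 0.0766). In the unfolded protein response list HSPA5 (0.28), HERPUD1 (0.35 ± 0.08), DNAJB9 (0.36 ± 0.07), SEL1L (0.39 ± 0.10) and HYOU1 (0.37 ± 0.07), chaperones and degradation factors of the endoplasmic reticulum, rose among 14. 8 did when adjusted over the list alone, and the list was called upward (camera adjusted p = 7.32e-06, adjusted p = 0.0861 with an estimated correlation). TGFBI (0.46 ± 0.11), CCN2 (1.04 ± 0.18), THBS1 (1.14 ± 0.14) and TAGLN (0.78 ± 0.13) rose among 8 TGF-beta target genes, 4 also when adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.264 with an estimated correlation). That call was lost with scan day as a block (adjusted p = 0.0564), within scan day 2 (adjusted p = 0.0752), with the median over probe sets (adjusted p = 0.166) and without vector replicate 1 (adjusted p = 0.0629). DDIT3 (0.46 ± 0.10) and PPP1R15A (0.59 ± 0.12) rose among 15 ATF4 genes, 2 also over the list alone (list adjusted p = 0.0525). BAG3 rose (0.30 ± 0.07) among 7 heat shock genes (2 up and 1 down when adjusted over the list alone, list adjusted p = 0.73). CXCL8 rose (0.68 ± 0.11) and the NF-kB inhibitor NFKBIA fell (-0.43 ± 0.10) among 9 NF-kB genes (3 up and 1 down when adjusted over the list alone, list adjusted p = 0.0525).

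CCN1 rose (0.56 ± 0.10) while FOSB (-0.48 ± 0.09) and IER3 (-0.52 ± 0.08) fell among 11 immediate early genes (2 up and 4 down when adjusted over the list alone, list adjusted p = 0.071). The metallothioneins were shifted downward by a median of -0.18 (camera adjusted p = 0.0117, adjusted p = 0.469 with an estimated correlation), with all 8 below 0 and 0 past the test, also when adjusted over the list alone. This call was lost without mutant replicate 1 (adjusted p = 0.0564) or 2 (adjusted p = 0.131), within scan day 2 (adjusted p = 0.0518) and with the RNA quality covariate (adjusted p = 0.0559), and without probe sets of the suffix _x_at, which can bind transcripts of several genes, the list had an adjusted p of 0.981 in the other direction. Cholesterol synthesis genes were shifted downward by a median of -0.19 (camera adjusted p = 0.00255, adjusted p = 0.264 with an estimated correlation), with 0 of 10 past the test and 5 down when adjusted over the list alone. With fluidics station as a block that list missed the threshold (median -0.12, adjusted p = 0.058). IFI6 (-0.83 ± 0.17) and RIGI (-0.85 ± 0.13) fell among 19 interferon genes, as they did when adjusted over the list alone (list adjusted p = 0.071). Single calls were VEGFA (-0.47 ± 0.10) among 11 hypoxia genes, the kinase CDK1 (0.45 ± 0.09) among 18 cell cycle genes and PECAM1 (-0.51 ± 0.10) among 9 immune and endothelial markers. These 3 lists, with 3 up and 1 down, 1 up, and 1 down when adjusted over the list alone, had adjusted p-values of 0.0777, 0.45 and 0.387. None passed, over all genes or the list alone, among 15 hepatocyte function genes, 8 p53 targets and 8 fibroblast and stellate markers (list adjusted p = 0.402, 0.73 and 0.959).

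For mutant against vector limma called 808 genes, out of 3775 at an unadjusted p under 0.05. The count was 123 without mutant replicate 2, 1605, 154 and 99 without vector replicate 1, 2 and 3, and 494 and 450 without wild-type replicate 2 and 3, which enter the shared estimate of the spread. With scan day as a block 1663 genes were called and within scan day 2 1225, of which 1171 had the same sign on day 1, with a median change of 0.22 in that direction against 0.52 on day 2. The fall of ALDH8A1 came mostly from day 2 (-3.10, against -0.66 on day 1). So did the fall of GULP1 (-2.22, against -0.65) and the rise of LINC00973 (1.61, against 0.46). The other largest falls were larger on day 2 too. So were the other largest rises after that of TMPRSS6, such as those of AGR2 (2.71, against 1.40 on day 1) and ANG (1.77, against 0.80). For HSPA6 the days differed little (4.05, against 3.90). The called lists had medians of 0.12 and 0.12 on day 1 and day 2 (acute phase), 0.20 and 0.28 (unfolded protein response), 0.16 and 0.30 (TGF-beta), -0.13 and -0.21 (cholesterol synthesis) and -0.11 and -0.21 (metallothioneins). All 3 mutant arrays, but only vector replicate 1, were run on the first fluidics station. With station as a block 31 genes were called, 30 of them among the 808. All 808 kept their direction, their median change went from 0.50 to 0.44 and their median standard error from 0.101 to 0.115. Only the 6 arrays of the comparison gave 35 calls, and array weights gave 1572.

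Wild-type and mutant cDNA differed in 7 genes, all 7 higher with the wild-type. HSPA6 was higher by 1.87 ± 0.14 log2 (SE; 3.66-fold, adjusted p = 0.000312) and CXCL8 by 1.51 ± 0.11 (2.85-fold, adjusted p = 0.000312). Both rose against the vector with either cDNA, CXCL8 by 2.19 with the wild-type and 0.68 with the mutant. The cytokine IL11 was higher by 1.0 ± 0.12 (adjusted p = 0.0175), having risen by 1.0 with the wild-type and differed by 0.00 with the mutant. C11orf96 (0.90 ± 0.12, adjusted p = 0.0332), GPRC5A (0.71 ± 0.09, adjusted p = 0.0193), the proton pump subunit ATP6V0D2 (0.68 ± 0.09, adjusted p = 0.0193) and BAG3 (0.55 ± 0.07, adjusted p = 0.0175) followed. A second probe set of ATP6V0D2 had the opposite sign (-0.27) and did not pass. The second probe set of IL11 differed by 0.25 and that of C11orf96 by 0.14, the others of GPRC5A by 0.43 and -0.10, and these did not pass. Both probe sets of CXCL8 and of HSPA6 passed.

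6 lists were called in this comparison, all higher with the wild-type. They were the immediate early genes (median 0.17, camera adjusted p = 4.15e-10, adjusted p = 0.0861 with an estimated correlation), the heat shock genes (0.24, adjusted p = 7.32e-06, adjusted p = 0.0861 with an estimated correlation) and the metallothioneins (0.19, adjusted p = 5.07e-05, adjusted p = 0.312 with an estimated correlation). The NF-kB genes (0.05, adjusted p = 0.00714, adjusted p = 0.254 with an estimated correlation), the type I interferon genes (0.08, adjusted p = 0.0185, adjusted p = 0.254 with an estimated correlation) and the BMP-SMAD targets (0.15, adjusted p = 0.0324, adjusted p = 0.235 with an estimated correlation) were the others. Of their members BAG3 and CXCL8 passed over all genes. When adjusted over the list alone, 5 of 11 immediate early, 3 of 7 heat shock and 2 of 9 NF-kB genes were higher with the wild-type, and 0 of 8 metallothioneins, 19 interferon genes and 9 BMP-SMAD targets. CCN1 (0.62, adjusted p = 0.0924), FOSB (0.43), DUSP1 (0.33) and the chaperone HSPB1 (0.45) lay above 0 without passing. Without probe sets of the suffix _x_at the metallothionein list had an adjusted p of 0.783 and the NF-kB list one of 0.06. With fluidics station as a block the median of the heat shock genes was 0.03 (adjusted p = 0.00693), that of the immediate early genes 0.29 and that of the NF-kB genes 0.15. On day 1 and day 2 the medians were 0.25 and 0.24 (heat shock), 0.29 and 0.19 (immediate early), 0.33 and 0.15 (metallothioneins), 0.10 and 0.01 (NF-kB), 0.00 and 0.12 (interferon) and 0.03 and 0.13 (BMP-SMAD). The NF-kB call was also lost without wild-type replicate 1 (adjusted p = 0.0512). The interferon call was lost without wild-type replicate 2 (adjusted p = 0.0788) or 3 (adjusted p = 0.0525) or mutant replicate 2 (adjusted p = 0.246), and with chip lot (adjusted p = 0.129) or fluidics station (adjusted p = 0.297) as a block, and with the median over probe sets (adjusted p = 0.192). The BMP-SMAD call was lost without wild-type replicate 1 (adjusted p = 0.0747) or 2 (adjusted p = 0.0529) without mutant replicate 1 (adjusted p = 0.0509) or 3 (adjusted p = 0.0648), and with the median over probe sets (adjusted p = 0.0607).

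The other 14 lists were not called. Among them the BMP receptors, ligands and hepcidin regulators (adjusted p = 0.45), iron handling (0.508), acute phase (0.953), unfolded protein response (0.399), ATF4 (0.927), TGF-beta targets (0.851) and cholesterol synthesis (0.435) had 0 members past the test, and 1 ATF4 gene was higher when adjusted over the list alone. The same held for hepatocyte function (adjusted p = 0.381), cell cycle (0.844), p53 targets (0.071), hypoxia (0.446), transmembrane proteases and inhibitors (0.518), immune and endothelial markers (0.397) and fibroblast and stellate markers (0.161), of which 1 cell cycle gene was lower with the wild-type when adjusted over the list alone. Limma found 1366 genes at an unadjusted p under 0.05. The count of 7 became 2, 3 and 2 without wild-type replicate 1, 2 and 3, 3, 2 and 4 without mutant replicate 1, 2 and 3, and 2 without vector replicate 3. It was 3 with chip lot and 4 with fluidics station as a block, 3 of them among the 7, whose median difference was 0.90 without and 0.97 with the station block. Within scan day 2 limma called 0 genes, with 1953 at an unadjusted p under 0.05, and camera called 4 lists there, with the BMP-SMAD targets (adjusted p = 0.0619) and the NF-kB genes (adjusted p = 0.0518) lost. On day 1, where all 3 arrays shared chip lot and station, the 7 genes were higher with the wild-type by 2.09 (HSPA6), 1.62 (CXCL8), 1.2 (IL11), 0.80 (C11orf96), 0.75 (GPRC5A), 0.85 (ATP6V0D2) and 0.63 (BAG3). Their direction there was fixed in advance, since these arrays entered the calls and the groups do not overlap in any of the 7 genes.

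Both responses were then compared across genes, which are not independent replicates. Of the calls against the vector, 93 genes were higher and 151 lower with either cDNA, and 0 went in opposite directions. Independent lists of these sizes would share 2.36 and 4.33 genes, a value that leaves out the shared vector arrays and so is too low a comparison. The log2 changes correlated at 0.827, against a mean of 0.50 in 100 simulations of unchanged groups set against shared vector arrays. The covariance was 0.0308 against a simulated 0.00543, a difference of 0.0254, and 74.9% of genes had the same sign against a simulated 66.6%. The simulated genes varied independently, so the simulated values do not cover deviations of the vector arrays that many genes share. The 3 vector arrays are too few to give each cDNA 2 vector arrays of its own, so part of the excess may come from the shared controls. The 244 shared calls became 36, 37 and 51 without wild-type replicate 1, 2 and 3, 116 without mutant replicate 2, and 714, 40 and 31 without vector replicate 1, 2 and 3. By the F test 482 genes differed among the 3 groups, with 3287 at an unadjusted p under 0.05. That count was 198, 159 and 189 without wild-type replicate 1, 2 and 3, 234 without mutant replicate 2, and 1053, 68 and 38 without vector replicate 1, 2 and 3.

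**Figure D3:**
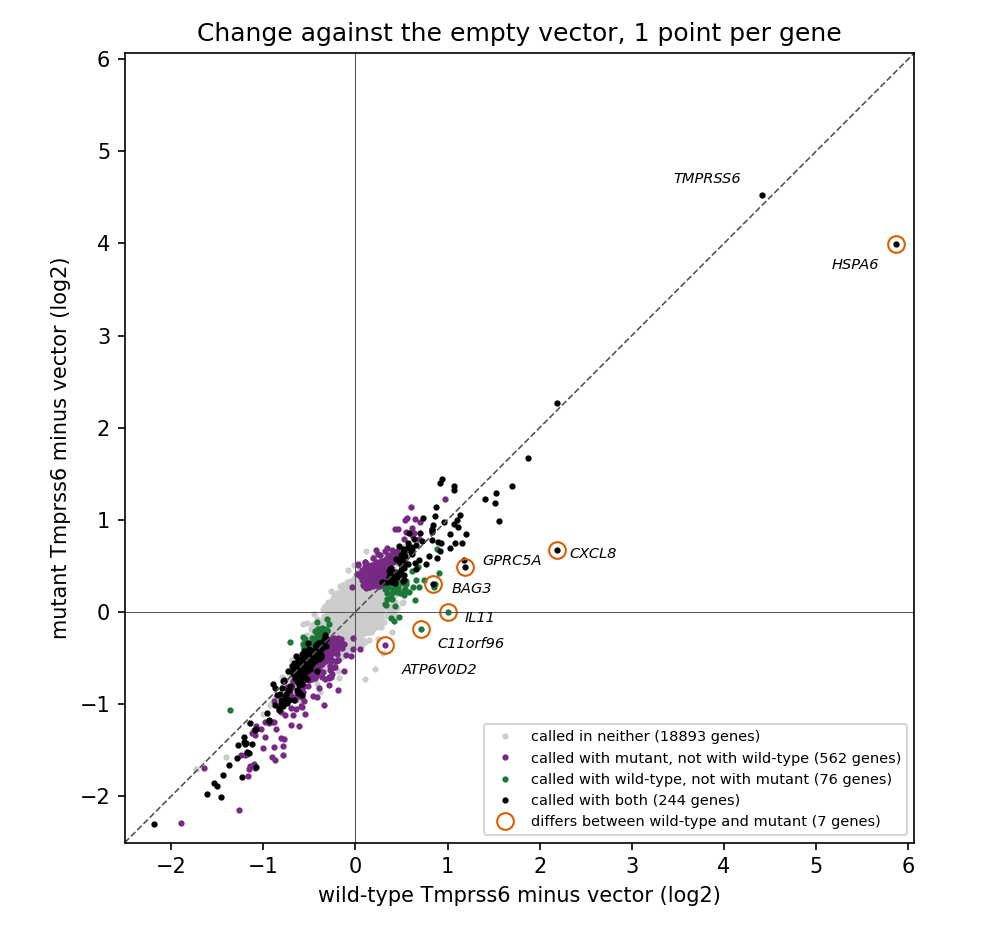
Log2 change against the vector with the wild-type cDNA (horizontal axis) and with the mutant cDNA (vertical axis), 1 point per gene, coloured by the calls, with a dashed line of equal change. The 244 genes called with both lie in the same direction on both axes, and the 7 circled genes, such as CXCL8 and HSPA6, lie below the line.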

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

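Probe sets without a single gene symbol were left out of the comparisons above and carried signals of their own. Limma called 52 of 13578 such probe sets for wild-type against vector (24 higher, 28 lower), 132 for mutant against vector (43 higher, 89 lower) and 1 for wild-type against mutant. That 1, which the annotation pairs with several genes, was higher by 0.77 ± 0.08 log2 (SE), and by 1.01 with the wild-type cDNA against the vector.

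Among them, a probe set that the annotation used here does not list rose by 9.52 log2 with the wild-type and by 9.31 with the mutant cDNA. Its signal was 12.05 ± 0.14 (SD, n = 3) and 11.84 ± 0.21 (SD, n = 3) against 2.53 ± 0.26 (SD, n = 3) with the vector, and wild-type minus mutant was 0.21 ± 0.14 (SE). The vector signal lies near the lower end of the array, where RMA compresses differences, so both rises are best read as lower bounds. Its gene is not named here, and no explanation was tested. With 3 arrays per group, single arrays were not tested as outliers.

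The first pattern weighed is the set of genes that differ between either cDNA and the vector. The tests of scan day, and of RNA quality beside it, were chosen after the result was seen for both comparisons. Each group had 1 array of day 1 and 2 of day 2, so a day effect common to all groups cancels. Had the differences arisen on day 2 alone, independent genes called there would take their day 1 sign at random. Of these genes, which are not independent, 96.2% of 236 for wild-type and 95.6% of 1225 for mutant kept it. Most thus recurred in direction on day 1, where a single vector array serves both comparisons. The median change of these genes, however, was 0.39 on day 1 against 0.70 on day 2 for wild-type and 0.22 against 0.52 for mutant. Choosing genes on day 2 enlarges their day 2 values, so how much of that gap follows the day stays open. Vector replicate 1, the vector array of day 1, also lay closer to the cDNA arrays on the first principal component (5.63, against 26.2 and 18.4 for replicates 2 and 3). A difference in RNA quality between the groups could be a further source, and this stays open. The GAPDH 3' minus 5' difference was 0.042 ± 0.019 (SD) with the wild-type, 0.056 ± 0.017 with the mutant cDNA and 0.060 ± 0.028 with the vector. For ACTB and GAPDH alike the gaps between the vector and either cDNA were smaller than the SD of the vector group. For ACTB that SD includes the gap between the days, and within each day every vector array lay above every cDNA array. The values were 0.260 against 0.168 and 0.236 on day 1, and 0.461 and 0.495 against 0.293 to 0.407 on day 2. GAPDH showed no such order. The ACTB difference followed the scan day, at 0.168 to 0.260 on day 1 and 0.293 to 0.495 on day 2, so a fit with it alone mostly removes the day. In that fit the median change of the called genes was 0.933 and 0.941 of its size without it, and 220 of 320 and 614 of 808 stayed called. With scan day beside it these shares were 0.832 and 0.725, the medians went from 0.55 to 0.46 and from 0.50 to 0.36 with median standard errors of 0.109 and 0.117, and 13 and 2 genes stayed called. All 320 and 808 genes kept their sign, but 9 arrays are too few to part RNA quality from the day and the groups. With fluidics station as a block 30 of the 808 mutant genes stayed called, while all 808 kept their direction. Their median change went from 0.50 to 0.44 and the median standard error from 0.101 to 0.115, so the calls ended through a slightly smaller change and a wider error together. All mutant arrays share the first station with only 1 vector array, so how much the station adds to the size stays open. In the wild-type and vector groups the station followed the scan day exactly, so the station block cannot be parted from the day. The 10 splits of each pair of groups are too few for a share under 0.05. The real splits gave 320 and 808 genes, each the only one (1 of 10) with as many, and the highest other gave 1 in both. For the F test, 1 of 100 splits, the real one with 482 genes, gave as many. The splits ignored scan day and took the arrays as independent units, so they cannot exclude a chance difference between single cultures. The highest other count, 414, came from 1 of 3 drawn splits that kept the vector arrays together and mixed the cDNA arrays, which points to cDNA against vector as the main structure.

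The second pattern is the 7 genes higher with the wild-type than with the mutant cDNA, led by HSPA6 and CXCL8, whose test of the transcript level was chosen after the result was seen. A lower level of the mutant transcript may be the simplest explanation, but the 95% interval of the TMPRSS6 probe set ends at 0.25 log2 in favour of the wild-type, below the bound of 0.5 set for it. A scan day effect common to both groups cancels here too, since both were spread alike over the days. Of the 100 genes with the smallest p on day 2, 87% had the same sign on day 1, although 0 genes were called on day 2 alone. The real split gave 7 genes and the highest other of the 10 splits gave 0 (1 of 10 with as many), too few splits for a share under 0.05. The protein level and activity of either form were not measured, so they stay open. With fluidics station as a block 3 of the 7 genes stayed called, their median difference went from 0.90 to 0.97 and the median standard error from 0.110 to 0.129, so over the 7 genes the error widened while the median difference did not shrink. The station block cannot be parted from the scan day here either. A difference in the stress response to the wild-type and the mutant protein remains a hypothesis.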

How the results depend on the processing

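All 320, 808 and 7 genes called for wild-type against vector, mutant against vector and wild-type against mutant kept their direction under loess, median centring, the prior, array weights, every block, the RNA quality covariate and each array left out. Much of this was fixed in advance. The groups did not overlap in 320, 807 and 7 of these genes, so weighting or leaving out arrays keeps their sign. The prior and the balanced blocks of scan day and replicate number leave the differences unchanged. Under the median over probe sets 315 of 320, 787 of 808 and 7 of 7 did and 220, 544 and 4 stayed called, and without probe sets of the suffix _x_at 314 of 316, 791 of 795 and 7 of 7. With the RNA quality covariate 220, 614 and 7 stayed called. The scan day 2 fit, the _x_at fit and the covariate were chosen after seeing the data. Counts moved, and the cause was not tested unless named. In the order of the 3 comparisons and the F test, where given, array weights gave 1061 and 1572 with 1277 by F, and scan day as a block 565 and 1663 with 934 by F. Fluidics station as a block gave 573, 31 and 4, and chip lot as a block 3 for wild-type against mutant. Scan day 2 alone gave 1225 for mutant against vector and 0 for wild-type against mutant, and the 6 arrays compared gave 35 and 4. Both settings leave fewer arrays for the spread, yet the mutant count of 808 went up in the first and down in the second. A 2-fold minimum gave 46, 89 and 3 with 85 by F, and an adjusted p under 0.10 gave 587 and 1503 with 935 by F. The replicate numbers did not pair the samples, since the deviations of 3 of the 9 same-numbered pairs, all of replicate 2, did not correlate over 0.1 (range of all pairs -0.143 to 0.386). Replicates 1, which share scan day 1, and replicates 3 did, and 5 of 9 arrays correlated best with their own number. With the replicate number as a block 1216 genes were called for mutant against vector and 5 for wild-type against mutant, 4 of them among the 7, and the TGF-beta list lost its mutant call (adjusted p = 0.0628). Leaving out 1 array gave 40 to 844, 99 to 1605 and 2 to 8 genes, 38 to 1053 by F, and 31 to 714 shared calls. HAMP ranged from 0.82 to 0.99, 0.51 to 0.78 and 0.14 to 0.41 log2 over these fits. It was 0.75 (adjusted p = 0.0763) for mutant against vector with station as a block, and the 50th percentile filter removes it. The correlation of both responses ranged from 0.790 to 0.877 with 1 array left out and was 0.876 above the 50th percentile of signal, where dim genes are gone. List calls numbered 5 to 8, 4 to 7 and 4 to 6 with 1 array left out, 0, 0 and 0 with an estimated correlation, and 2 for mutant against vector on scan day 2. The next 3 results reversed. TMPRSS6 for wild-type against vector was -0.0334 (adjusted p = 0.881) without probe sets of the suffix _x_at, which removes its responding probe set. RASSF8 was 0.13 with the median over its probe sets, most of which did not change. The metallothionein list for mutant against vector had an adjusted p of 0.981 in the other direction without such probe sets. Of the other results for named genes 1981 stayed on their side of the threshold and 451 lost it, 66 of them without vector replicate 3 and 53 with station as a block. For lists 362 stayed and 28 lost it. Signal near the background limits dim genes, whose fold changes RMA compresses.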

Other observations

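The tests of the YAP and SRF target lists and of the length trend were chosen after the results they concern had been seen. The LIM-domain protein FHL2, named here after its values were seen, rose by 0.80 ± 0.10 log2 (SE) with the wild-type and by 0.61 ± 0.10 with the mutant cDNA, and FILIP1L by 0.53 ± 0.10 and 0.65 ± 0.10. Together with TAGLN they belong to the targets of the transcription factor SRF, of which 21 of 24 were measured. The 20 members other than TAGLN had a median of 0.16 with the wild-type and 0.12 with the mutant cDNA. Their shift with the wild-type cDNA had a camera p of 4.99e-06 with the preset correlation, and p = 0.00834 with an estimated correlation, which did not pass after adjustment over 6 tests. With the mutant cDNA camera gave p = 0.0153 with the preset and p = 0.0862 with an estimated correlation, and for wild-type against mutant p = 0.0121 and p = 0.0781. Apart from TAGLN, FHL2 and FILIP1L, none of the members passed, and some lay below 0. A rise of SRF targets as a whole may explain these genes in the wild-type comparison, but this is a hypothesis found and tested on the same arrays. FHL2 and FILIP1L, seen before the test, were also among the 20 members tested.

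CCN1, CCN2, ANKRD1 and AXL, which are targets of YAP, rose with both cDNAs, AXL by 1.10 ± 0.17 log2 (SE) and 0.99 ± 0.17. A rise of the whole YAP signature could be the reason, but its 17 other measured members had a median of 0.05 and a camera p of 0.187 with the preset correlation (p = 0.205 with an estimated correlation) in the wild-type comparison. With the mutant cDNA the median of these members was 0.01, and camera gave p = 0.925 with the preset and p = 0.923 with an estimated correlation, so neither comparison shows such a rise. GADD45A (0.39 ± 0.07) was the 1 called among them there and IGFBP3 (0.34 ± 0.07) with the mutant cDNA. A p that misses the threshold does not exclude a small rise.

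The third pattern weighed is the length of the genes that fell. The 183 of 185 genes lower with the wild-type cDNA that have a length spanned a median of 55.9 kb of the genome, against 24.7 kb for all genes. In 10000 random draws matched on signal the highest median was 43.7 kb and 0 were as long. With the mutant cDNA the 461 fallen genes spanned a median of 43.5 kb, again with 0 of 10000 draws as long, while the genes that rose spanned 22.2 and 26.8 kb. A general trend of fold change with length could produce part of this. After the trend was removed from every array, 158 genes were called lower with the wild-type, 152 of them among the 183, and their median length was 1.83 times that of all genes (95% bootstrap interval 1.16 to 2.51, against 2.26 times before). The interval reaches below the bound of 1.2 set for it, so this explanation stays open. Dim probe sets could produce it too, but among genes above the median signal the length of the fallen genes was 2.16 times that of all (95% bootstrap interval 1.71 to 2.78). The lengths come from assembly GRCh38.p14.

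HAMP rose although matriptase-2 is known as a repressor of hepcidin, which it exerts by cleaving the BMP co-receptor hemojuvelin (HJV). The signal of HJV, named here after its values were seen, lay between 2.91 and 3.27 log2 on all 9 arrays, at percentile 7.85 of the genes measured.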
